A study of Sinotaia aeruginosa with 24 samples.

How the data were processed

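RNA sequencing had been made, per the labels, from total RNA taken with an Rneasy mini plus kit (Qiagen) and prepared with the SMARTER mRNA-Seq kit. The deposited table held 1 value per gene cluster and sample for 233875 clusters and 24 samples. Per the file headers these are raw counts, and 3.54% to 7.14% of the values per sample were not whole, so they were taken to be expected counts (reads estimated per cluster), not scaled between samples. The assembler, aligner and counting tool are not given in the sources used. The submitters' processing notes list the mouse build mm10, which does not go with identifiers of an assembled snail transcriptome, and no coordinates were used. Names came from the annotation columns of the same table, as the best Swiss-Prot match, else the NR or KO description. The series design text names low, medium and high concentrations of each exposure, but the samples hold a single level of each, not stated in the labels.

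Values were rounded to whole counts and tested with edgeR 4.0.16 under R 4.3.3. Clusters passed filterByExpr at its default of 10 counts, which kept 55762 in liver, 64046 in brain and 78809 over both (98.7%, 98.6% and 98.97% of counts), scaled by TMM. A negative binomial model with 1 mean per group was fitted to the 12 samples of a tissue, and to all 24 for comparisons between tissues, with edgeR's robust quasi-likelihood test and Benjamini-Hochberg adjustment. A cluster was called at an adjusted p under 0.05, in either direction. Each treatment was set against the controls of its tissue, the combined exposure against each single one and against the sum of their log2 changes, the response of brain against that of liver, and control brain against control liver. Levels in comparisons between tissues come from the fit of all samples. With 3 samples against 3, a permutation of single values cannot go below p = 0.1. Where a group had no count, the fold is a bound from a floor of 3 counts over the group, which covers counting error only.

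Before the data were examined, the tests, the alternatives, the rule for named genes and the name patterns of the gene lists were fixed, of which 29 lists had members. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, for lists of at least 5 tested members, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. No cluster carried the name metallothionein, so that list stayed empty. The rule took, among called clusters with an informative name, at least 5 CPM in the higher group and, for treatments and control tissues, no overlap of the groups, the 8 with the largest change each way (4 in other comparisons), 1 per product name. It added up to 2 called members per list and direction with the smallest adjusted p, and always the 70 kDa heat shock gene with the smallest p and the most abundant acetylcholinesterase. The rule gave 1005 pairs of gene and comparison, 978 of them called, 526 kept their call whichever library was left out, and the text names 147, 128 of them called. These were chosen after their values were seen, mostly among calls kept in every omission, so they stand firmer than the rest.

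The alternatives were no filter on low counts, a stricter filter (1 CPM in 3 samples), DESeq2 1.42.0 size factors, the DESeq2 Wald test, the replicate number as a term, only the 6 samples compared, an added log2 fold change of 1 and the omission of each sample. Where an omission left a group with fewer samples, the fit pooled the spread over all groups. The procedure was tested on simulated counts with 200 changed genes of folds 2, 4, 8 and 16. In that order edgeR recovered 18, 40, 64 and 80% for cadmium in liver (5 false of 106 calls), 4, 36, 72 and 70% for cadmium in brain (6 of 97) and 0, 16, 26 and 38% for the tissue difference under cadmium (1 of 41), and called 0 where nothing was changed. Covariances and correlations between treatments were set beside 5 simulations of unchanged groups, and overlaps beside independent lists.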

Results

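Freshwater snails, labelled Sinotaia aeruginosa and called Bellamya aeruginosa in the series title, had been fed algae carrying cadmium, polystyrene microplastic or both. The series asked how the combined exposure acts beside each pollutant alone. RNA came on day 42 from 2 tissues, labelled liver and brain, of unexposed, cadmium-fed, polystyrene-fed and combined-exposure snails, with 3 samples in each of the 8 groups. The labels do not say that the samples of a group came from separate animals, so the p-values measure the spread between these samples. Nor do they state the concentration behind an exposed group. Samples held 10 or more expected counts in 44601 to 57751 gene clusters. Each name below is the best database match of a cluster, so it gives the family, not a proven orthologue. Clusters of near-identical copies may share reads. Levels are counts-per-million values (CPM) as mean ± SD with n = 3, and log2 fold changes stand with their standard errors. Libraries left out are named by treatment and replicate number. Every adjusted p called edgeR's is from its quasi-likelihood test with Benjamini-Hochberg adjustment.

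On the first principal component, which held 24.5% of the variance in liver and 24.6% in brain, the controls lay on one side and all treated samples on the other. The second, with 16.03% and 17.4%, set the combined exposure apart from cadmium. Brain control replicate 5 stood furthest out, with a mean correlation across genes of 0.884 to its own group against 0.917 and 0.912 for the other two. It held 67481 CPM of mitochondrially encoded transcripts, where the other control brains held 32215 and 31727.

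**Figure D1:**
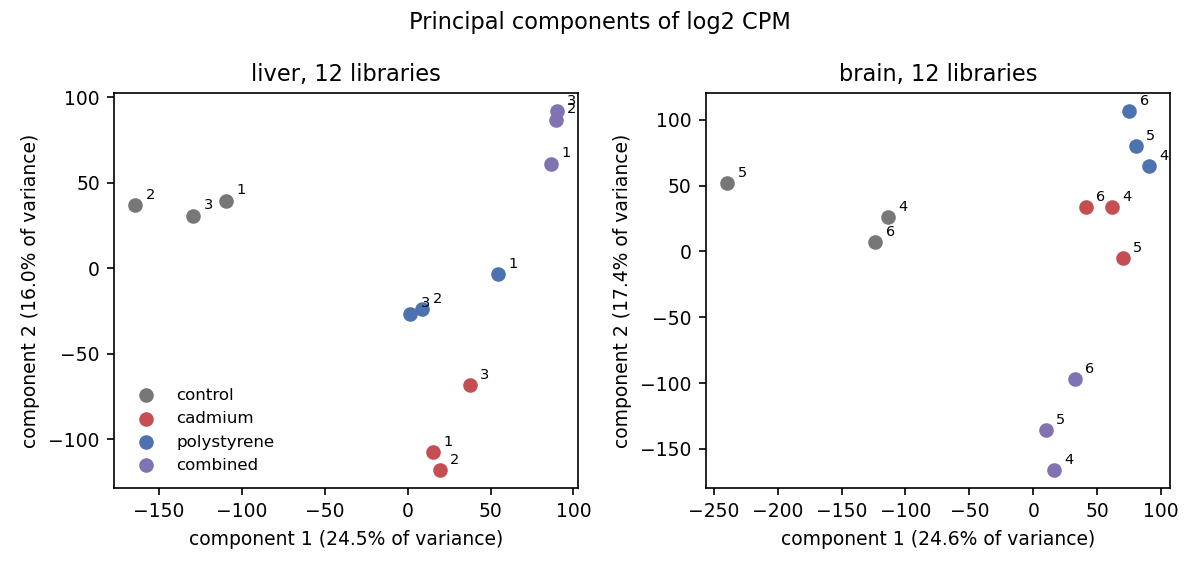
First and second principal components of log2 CPM for the 12 liver and the 12 brain libraries, 1 point per library with its replicate number. Controls lie on the negative side of component 1 (24.5% of variance in liver, 24.6% in brain) and all treated libraries on the positive side.

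In liver, heat shock genes, whose proteins hold or refold other proteins, shifted upward with cadmium. Heat shock protein beta-6 (Cluster-2499.98256, 42.9 ± 7.05 against 16.4 ± 0.999 CPM, log2 fold change 1.39 ± 0.22, edgeR adjusted p = 0.00639) rose. So did Heat shock protein beta-1 (Cluster-2499.82162, 27.5 ± 4.36 against 11.6 ± 1.1 CPM, edgeR adjusted p = 0.00109). Of 32 heat shock genes 5 rose and none fell (9 adjusted over the list alone), and the list shifted upward (camera adjusted p = 0.00154, adjusted p = 0.228 with an estimated correlation). The number higher was 2 without cadmium 1 or 2 or control 2 or 3 or polystyrene 3 and 3 without control 1. Glutaredoxin (Cluster-2499.63316, 2.37 ± 0.523 against 0.12 ± 0.0442 CPM, edgeR adjusted p = 7.30e-04), which reduces disulphides with glutathione, rose. Cytochromes P450, which oxidise foreign compounds and lipids, moved both ways. P450 3A6 (Cluster-2499.103464, 59.2 ± 5.75 against 28.9 ± 6.09 CPM, edgeR adjusted p = 0.00178) rose and P450 3A24 (Cluster-2499.79531, 21.3 ± 2.97 against 40.1 ± 4.3 CPM, adjusted p = 0.00769) fell. In innate defence, Mannan-binding lectin serine protease 1 (Cluster-2499.139351) rose (log2 fold change 4.45 ± 0.54, edgeR adjusted p = 0.00433). The lectin Ficolin-1 (Cluster-2499.78628, 9.4 ± 0.849 against 2.73 ± 1.2 CPM, edgeR adjusted p = 0.00229) rose too, while Ficolin-2 (Cluster-2499.90340, 3.78 ± 1.71 against 35.5 ± 6.86 CPM, adjusted p = 8.40e-04) fell. Of the caspase inhibitors, Baculoviral IAP repeat-containing protein 3 (Cluster-2499.108892, 23.1 ± 11.1 against 3.77 ± 0.44 CPM, edgeR adjusted p = 0.00413) rose. An Inhibitor of apoptosis protein (Cluster-2499.76001) fell (log2 fold change -1.87 ± 0.31, edgeR adjusted p = 0.00534). Perivitellin-2 (Cluster-2499.69505), an egg protein of related snails, fell as well (log2 fold change -5.32 ± 0.55, edgeR adjusted p = 7.70e-04).

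Muscle genes shifted upward in the cadmium livers, with 5 of 54 members higher (8 adjusted over the list alone, camera adjusted p = 0.00154, adjusted p = 0.546 with an estimated correlation). They summed to 2201 ± 218 against 1777 ± 71.2 CPM. The number higher was 0 without control 2, 1 without cadmium 1, 2 without cadmium 3 and 3 without control 1 or 3. Ciliary genes shifted downward with 2 of 118 members lower (camera adjusted p = 3.45e-06, adjusted p = 0.826 with an estimated correlation), lost without control 2 (camera adjusted p = 0.078). The number lower was 0 without cadmium 1 or 2 or 3 or combined 3 or control 2 or 3 or polystyrene 2 and 1 without combined 1 or 2 or polystyrene 3, that higher 0 and 2 without cadmium 3. Sperm and testis genes shifted with none of 38 lower (camera adjusted p = 0.0253, adjusted p = 0.724 with an estimated correlation), lost without control 2 or cadmium 3 (camera adjusted p up to 0.363). In all, 1930 of 55762 tested clusters differed from the control livers, 926 higher and 1004 lower. The count was 568 without control 2, 774 without cadmium 1, 1026 without cadmium 2, 1074 without control 3 and 2969 without combined 1.

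In livers of polystyrene-fed snails, Globin (Cluster-2499.89295, 122 ± 12.1 against 203 ± 30.8 CPM, log2 fold change -0.74 ± 0.13, edgeR adjusted p = 0.00900) and Hemocyanin 2 (Cluster-2499.88454, 412 ± 61.3 against 767 ± 175 CPM, adjusted p = 0.0475), the copper-based oxygen carrier of molluscan blood, fell. Of 32 oxygen carriers these 2 passed, and the list shifted downward (5 lower adjusted over the list alone, camera adjusted p = 0.0227, adjusted p = 0.917 with an estimated correlation). Globin lost its call without polystyrene replicate 2 (edgeR adjusted p = 0.0547) and Hemocyanin 2 in 8 of 12 omissions (adjusted p up to 0.167). The list call was lost without control 3 or polystyrene 3 (camera adjusted p up to 0.392), and the number lower was 0 without polystyrene 2, 1 without cadmium 2 or combined 2 or 3 or control 2 or 3 or polystyrene 1 or 3 and 4 without cadmium 3. Sulfotransferase 1B1 (Cluster-2499.90183, 15.04 ± 1.43 against 24.6 ± 0.809 CPM, edgeR adjusted p = 0.00804), which adds sulphate to phenols, fell. So did P450 3A24 (20.6 ± 3.12 against 40.1 ± 4.3 CPM, edgeR adjusted p = 0.00584). Hemocytin (Cluster-2499.87352, 0.701 ± 0.234 against 275 ± 170.1 CPM, edgeR adjusted p = 8.42e-04), a blood cell lectin in insects, fell. SCO-spondin (Cluster-2499.89586), a secreted glycoprotein at 413 ± 283 CPM in controls, had no count left, at least 6856-fold lower (edgeR adjusted p = 0.0033). Glutaredoxin rose (4.63 ± 1.33 against 0.12 ± 0.0442 CPM, log2 fold change 5.19 ± 0.48, edgeR adjusted p = 2.33e-04). So did the matrix genes Collagen alpha-4(VI) chain (Cluster-2499.80169, 149 ± 17.3 against 83.1 ± 6.93 CPM, edgeR adjusted p = 0.00204) and Cartilage matrix protein (Cluster-2499.87991, 96.3 ± 2.03 against 60.2 ± 5.2 CPM, adjusted p = 0.00523).

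Muscle genes shifted upward, 4 of 54 members higher (8 adjusted over the list alone, camera adjusted p = 0.00762, adjusted p = 0.454 with an estimated correlation), lost without control 2 (camera adjusted p = 0.0543). Single omissions left the number higher at 0 without control 2 or polystyrene 3, 1 without control 3 or polystyrene 2 and 2 without polystyrene 1. Ribosomal proteins shifted downward with 1 of 99 members higher and none lower (camera adjusted p = 0.0196, adjusted p = 0.917 with an estimated correlation). That call was lost without control 1, polystyrene 2 or polystyrene 3 (camera adjusted p up to 0.202), and the number higher was 0 without cadmium 1 or control 1 or 2 or 3 or polystyrene 1 or 2 or 3. Ciliary genes also shifted downward, none of 118 lower (camera adjusted p = 0.0332, adjusted p = 0.917 with an estimated correlation). Theirs was lost in 8 of 12 omissions (camera adjusted p up to 0.975). Polystyrene changed 1750 clusters in liver, 882 upward and 868 downward. Leaving out 1 library gave 570 without control 2, 597 without polystyrene 2, 609 without polystyrene 3, 895 without polystyrene 1, 903 without control 3 and 2708 without combined 1.

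Under combined exposure, ciliary genes and genes of sperm and testis shifted downward in liver. Neither list passed with an estimated correlation (camera adjusted p = 0.446 for both). Of 118 ciliary genes 31 fell and 2 rose (66 and 2 adjusted over the list alone, camera adjusted p = 2.22e-21). They summed to 490.1 ± 30.2 against 1191 ± 514 CPM. Cilia- and flagella-associated protein 61 (Cluster-2499.59043, 0.824 ± 0.268 against 6.6 ± 3.94 CPM, edgeR adjusted p = 0.00558) and protein 77 (Cluster-2499.52633, 0.452 ± 0.133 against 4.86 ± 3.16 CPM, adjusted p = 0.00733) of the axoneme fell. A cluster of the motor Dynein axonemal heavy chain 10 (Cluster-2499.71291, 6.29 ± 4.38 against 0.576 ± 0.171 CPM, edgeR adjusted p = 0.00624) rose. Spermatogenesis-associated protein 1 (Cluster-2499.108246, 0.509 ± 0.302 against 4.4 ± 2.48 CPM, edgeR adjusted p = 0.00843) fell. In all 5 of 38 sperm and testis genes did (15 adjusted over the list alone, camera adjusted p = 3.26e-04). The number of lower ciliary genes was 5 without combined 3, 7 without combined 2, 8 without control 2, 10 without combined 1, 13 without control 3, 18 without polystyrene 2 and 20 without cadmium 1, of higher ones 1 without control 2 or 3. That of sperm and testis genes was 1 without combined 1 or 2 or 3 or control 2, 2 without control 3, 3 without cadmium 1 or 2 or polystyrene 2, 8 without polystyrene 1 and 10 without control 1. Single control livers held 732, 1746 and 1096 CPM of ciliary genes. Whether other tissue in the samples lies behind these shifts was not tested.

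Muscle genes rose, 15 of 54 members (21 up and 1 down adjusted over the list alone, camera adjusted p = 1.30e-05, adjusted p = 0.446 with an estimated correlation). They summed to 2357 ± 37.9 against 1777 ± 71.2 CPM, and the number higher was 5 without control 2 and 8 without control 3. Myosin heavy chain (Cluster-2499.89777, 269 ± 14.6 against 158 ± 15.5 CPM, edgeR adjusted p = 0.00318) and Twitchin (Cluster-2499.61166, 12.3 ± 2.35 against 4.67 ± 1.04 CPM, adjusted p = 0.00285), a giant muscle protein, were among them. The matrix gene Collagen alpha-4(VI) chain rose too (177 ± 4.53 against 83.1 ± 6.93 CPM, edgeR adjusted p = 3.14e-04). Heat shock protein beta-6 and Alpha-crystallin B chain (Cluster-2499.83254, 38.1 ± 4.89 against 16.7 ± 1.9 CPM, edgeR adjusted p = 0.00249), both small heat shock proteins, rose (beta-6 64.9 ± 24.3 against 16.4 ± 0.999 CPM, adjusted p = 7.19e-04). Zinc importers ZIP2 (Cluster-2499.79570, 125 ± 27.04 against 47.7 ± 10.1 CPM, edgeR adjusted p = 0.00158) and ZIP3 (Cluster-2499.85387, 36.02 ± 6.28 against 12.6 ± 4.4 CPM, adjusted p = 0.00257) rose. Among detoxifying enzymes a P450 monooxygenase (Cluster-2499.85831, 14.1 ± 1.73 against 7.16 ± 0.185 CPM, edgeR adjusted p = 0.00607) rose and Glutathione S-transferase omega-1 (Cluster-2499.90716, 19.5 ± 0.681 against 30.4 ± 0.988 CPM, adjusted p = 0.00591) fell. P450 3A24 (19.9 ± 3.46 against 40.1 ± 4.3 CPM, edgeR adjusted p = 0.00345) and Sulfotransferase 1B1 (15.1 ± 1.29 against 24.6 ± 0.809 CPM, adjusted p = 0.00625) fell too. Globin fell (115 ± 16.7 against 203 ± 30.8 CPM, edgeR adjusted p = 0.00366), 1 of 4 lower oxygen carriers of 32 (camera adjusted p = 8.97e-04, adjusted p = 0.525 with an estimated correlation). The list call was lost without control 3 (camera adjusted p = 0.116), and the number lower was 1 without combined 1 or 2 or control 2 or 3, 2 without polystyrene 1 or 2 or 3 and 8 without cadmium 3 or control 1.

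Tissue-type plasminogen activator (Cluster-2499.139706, 49.6 ± 46.8 CPM, at least 716-fold higher, edgeR adjusted p = 0.0135) and Receptor-type tyrosine-protein phosphatase kappa (Cluster-2499.164518, 6.75 ± 3.14 CPM, at least 96.1-fold higher, adjusted p = 7.19e-04) had no count in control livers and rose. Perivitellin-2 fell (0.178 ± 0.0992 against 23.5 ± 11.5 CPM, edgeR adjusted p = 3.42e-04), in an egg and germ line list with 2 higher and 3 lower of 17 (camera adjusted p = 0.0481, adjusted p = 0.446 with an estimated correlation). That list call was lost in 6 of 12 omissions (camera adjusted p up to 0.21), and every omission left 0 to 1 higher. Chaperones of the endoplasmic reticulum shifted downward with 3 of 17 lower (camera adjusted p = 0.0456, adjusted p = 0.525 with an estimated correlation), a call lost in 11 of 12 omissions (camera adjusted p up to 0.345). The number lower was 0 without combined 2 or 3 or control 1 or 3 and 1 without control 2 or polystyrene 2. Combined exposure changed 3482 clusters in liver, 1593 higher and 1889 lower. The count was 2267 in a fit of the 6 samples alone, 1058 without control 2, 1712 without combined 3, 1867 without control 3 and 2007 without combined 2.

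Against cadmium alone, chaperones of the endoplasmic reticulum, where secreted proteins fold, shifted downward in the combined livers. BiP (Cluster-2499.85374, 134 ± 11.1 against 250.4 ± 56.2 CPM, log2 fold change -0.91 ± 0.15, edgeR adjusted p = 0.0098), which binds unfolded proteins, was lower. It was 1 of 6 lower of 17 such chaperones (8 adjusted over the list alone, camera adjusted p = 2.73e-05, adjusted p = 0.812 with an estimated correlation). Also lower were Baculoviral IAP repeat-containing protein 3 (2.29 ± 0.844 against 23.1 ± 11.1 CPM, edgeR adjusted p = 0.00259) and P450 3A6 (25.8 ± 2.29 against 59.2 ± 5.75 CPM, adjusted p = 0.00117). The chlorophyll-cleaving Chlorophyllase-2 (Cluster-2499.85110, 128 ± 29.5 against 261 ± 20.1 CPM, edgeR adjusted p = 0.00535) was lower too. Higher were the chitin-cleaving Acidic mammalian chitinase (Cluster-2499.85451, 29.9 ± 3.56 against 14.9 ± 1.1 CPM, edgeR adjusted p = 0.0049) and ZIP8 (Cluster-2499.89166, 47.7 ± 8.35 against 24.8 ± 4.97 CPM, adjusted p = 0.0089), whose mammalian relative carries zinc and cadmium. Ficolin-2 was higher as well (26.7 ± 9.39 against 3.78 ± 1.71 CPM, edgeR adjusted p = 0.00279). Ciliary genes shifted downward with 2 higher and 1 lower of 118 (camera adjusted p = 5.17e-08, adjusted p = 0.812 with an estimated correlation). In total 1393 clusters differed, 622 higher and 771 lower. Their number was 623 in a fit of the 6 samples, 442 without combined 3, 479 without cadmium 1, 605 without cadmium 2 and 765 without combined 2.

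Against polystyrene alone, the combined livers held less Glutaredoxin (0.875 ± 0.308 against 4.63 ± 1.33 CPM, edgeR adjusted p = 0.00652) and more Ficolin-1 (18.6 ± 1.91 against 5.69 ± 1.02 CPM, adjusted p = 0.0038). The scaffold protein SASH1 (Cluster-2499.96190, 0.783 ± 0.331 against 44.1 ± 13.7 CPM, edgeR adjusted p = 1.36e-04) was lower. Ciliary genes shifted downward with 2 lower and 1 higher of 118 (44 and 2 adjusted over the list alone, camera adjusted p = 3.33e-18). Sperm and testis genes did with 1 and ABC transporters with 1 lower (camera adjusted p = 0.00206 and 0.0137). With an estimated correlation camera gave each an adjusted p = 0.716. Heat shock genes and ribosomal proteins shifted upward with 1 and 0 higher (camera adjusted p = 0.0119 and 2.26e-05, adjusted p = 0.716 and 0.906 with an estimated correlation). Altogether 736 clusters differed, 274 higher and 462 lower. The count was 219 without polystyrene 3, 225 without polystyrene 2, 249 without combined 3, 478 without combined 2 and 1141 without combined 1.

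A test of additivity asked whether the combined exposure departed from the sum of the separate log2 changes. Controls that differ from all treated samples also give a departure, which was not separated out. In liver, Baculoviral IAP repeat-containing protein 3 stood at 3.77 ± 0.44 CPM in controls, 23.1 ± 11.1 with cadmium, 5.84 ± 2.17 with polystyrene and 2.29 ± 0.844 with both (departure -3.96 ± 0.54, edgeR adjusted p = 0.00579). Glutaredoxin stood at 0.12 ± 0.0442 CPM in controls, 2.37 ± 0.523 with cadmium, 4.63 ± 1.33 with polystyrene and 0.875 ± 0.308 with both (departure -6.61 ± 0.61, edgeR adjusted p = 5.87e-04). P450 3A6 (departure -1.12 ± 0.20, edgeR adjusted p = 0.0132) also lay below the sum. Above it were Acidic mammalian chitinase (departure 1.39 ± 0.21, edgeR adjusted p = 0.00579) and Ficolin-2 (departure 3.03 ± 0.43, adjusted p = 0.00792). In all, 995 clusters departed, 454 upward and 541 downward, and no gene list shifted by camera. The count was 448 without polystyrene 2, 479 without polystyrene 3, 503 without cadmium 1, 521 without control 2, 630 without combined 3 and 1723 without combined 1.

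**Figure D2:**
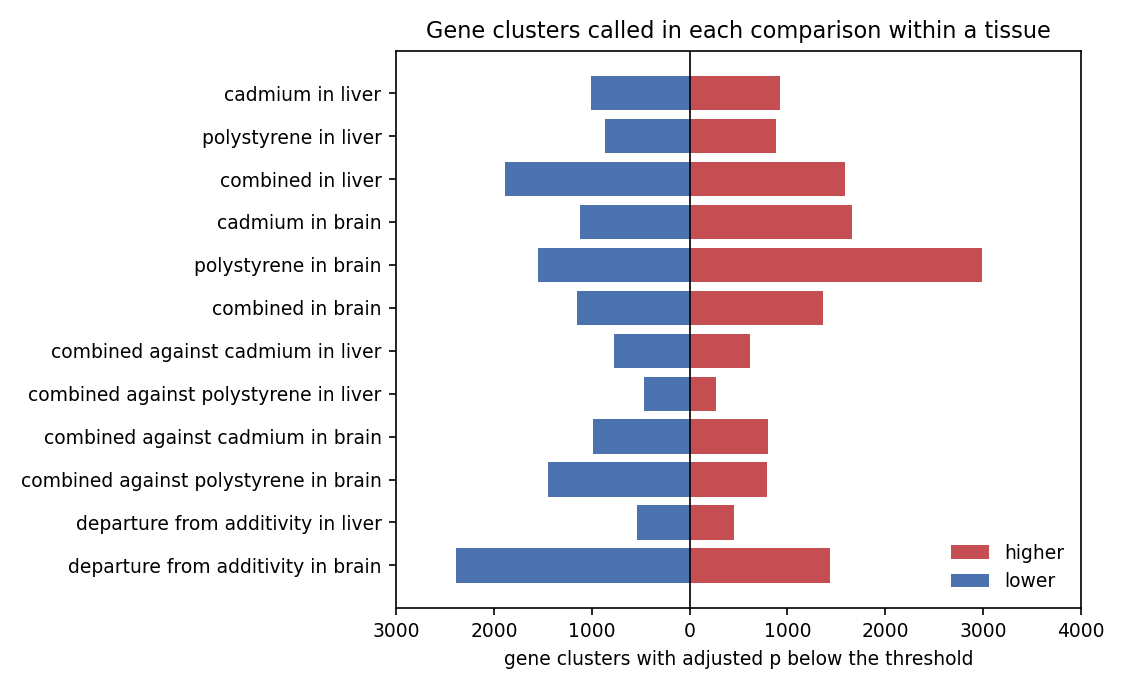
Gene clusters past the threshold of edgeR's test in the comparisons within a tissue, numbers higher to the right of 0 and lower to the left. Polystyrene in brain has the most, 2987 higher and 1549 lower, and combined exposure against polystyrene in liver the fewest, 274 higher and 462 lower.

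In brain, innate immunity genes and heat shock genes shifted upward with cadmium. Of 355 immunity genes 43 rose and 6 fell (84 and 13 adjusted over the list alone, camera adjusted p = 8.11e-09, adjusted p = 0.688 with an estimated correlation). The rising ones numbered 26 without cadmium 5 and 27 without cadmium 4, the falling ones 3 without cadmium 4. Complement C1q-like protein 4 (Cluster-2499.20590, 10.7 ± 2.34 against 0.131 ± 0.13 CPM, edgeR adjusted p = 7.64e-04), of a family of complement recognition proteins, and the immune GTPase IMAP family member 9 (Cluster-2499.119048, 17.1 ± 2.63 against 4.001 ± 0.947 CPM, adjusted p = 7.36e-04) rose. Among chaperones Heat shock protein 70 B2 (Cluster-2499.57688, 118 ± 90.7 against 10.1 ± 4.77 CPM, log2 fold change 3.54 ± 0.59, edgeR adjusted p = 0.00821) and HSP 90-beta (Cluster-2499.86504, 383 ± 12.96 against 173 ± 52.5 CPM, adjusted p = 0.00667) rose. In all 4 of 36 heat shock genes rose (12 adjusted over the list alone, camera adjusted p = 9.77e-06, adjusted p = 0.862 with an estimated correlation). Their number was 2 without cadmium 4 or 5 or 6 or control 5 or 6 and 8 without combined 4. Thrombomodulin (Cluster-2499.148402, 20.7 ± 7.74 CPM, at least 315-fold higher, edgeR adjusted p = 5.15e-04), a thrombin receptor in vertebrates, rose from no count in controls. So did an Inhibitor of apoptosis protein (Cluster-2499.95251, 3.14 ± 1.03 CPM, at least 47.3-fold higher, edgeR adjusted p = 4.57e-04). The executioner protease Caspase-3 (Cluster-2499.123164, 4.18 ± 1.15 against 22.7 ± 5.48 CPM, edgeR adjusted p = 0.00196) and the matrix protein Hemicentin-1 (Cluster-2499.94989, 0.0791 ± 0.0874 against 22.5 ± 10.2 CPM, adjusted p = 2.94e-04) fell. The lipid transporter ABCA3 (Cluster-2499.69072, 6.8 ± 2.25 against 0.977 ± 0.658 CPM, edgeR adjusted p = 0.00356) rose.

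Mitochondrially encoded clusters, which carry respiratory chain subunits, moved both ways, 11 of 90 up and 19 down (14 and 33 adjusted over the list alone). Their shift was downward (camera adjusted p = 1.06e-04, adjusted p = 0.862 with an estimated correlation), lost without control 5 (camera adjusted p = 0.103). The number lower was 10 without cadmium 5 and 11 without cadmium 4 or 6. The number higher was 6 without control 6 and 7 without cadmium 4 or 5. Of Cytochrome b, 1 cluster (Cluster-2499.82579, 85.5 ± 15.3 against 0.133 ± 0.231 CPM, edgeR adjusted p = 5.83e-05) rose. Another (Cluster-2499.80522, 0.367 ± 0.151 against 555 ± 519.8 CPM, edgeR adjusted p = 0.00319) fell. Cytochrome c oxidase subunit 1 (Cluster-2499.87407, 253 ± 47.4 against 7.11 ± 5.05 CPM, edgeR adjusted p = 3.07e-04) rose. NADH-ubiquinone oxidoreductase chain 4L (Cluster-2499.84200, 10.3 ± 1.48 against 282 ± 117 CPM, edgeR adjusted p = 2.20e-04) fell. ABC transporters (1 of 85 higher) and apoptosis genes (5 higher and 3 lower of 167) shifted too (camera adjusted p = 0.0117 and 0.00232, adjusted p = 0.955 and 0.867 with an estimated correlation). So did neuronal genes (1 of 262 higher), neurotransmitter enzymes and ribosomal proteins (none of 42 and 102; camera adjusted p = 0.0268, 0.0268 and 0.0186, adjusted p = 0.955, 0.862 and 0.955 with an estimated correlation). Those calls were lost without control 5 (camera adjusted p = 0.495), without control 5 (camera adjusted p = 0.116), in 4 of 12 omissions (camera adjusted p up to 0.22), in 8 of 12 omissions (camera adjusted p up to 0.369) and without control 5 or cadmium 5 (camera adjusted p up to 0.369), in that order. The number of higher apoptosis genes was 1 without cadmium 4 or control 5, 2 without control 6, 3 without cadmium 5 and 9 without combined 4, that of lower ones 1 without cadmium 4 or 5 or control 5 and 5 without combined 4. Higher ABC transporters numbered 2 without control 4 or 5, neuronal genes 2 without control 4 and 3 without control 6. Of 64046 tested clusters 2782 differed, 1662 higher and 1120 lower. Single omissions gave 1280 without cadmium 4, 1616 without cadmium 5, 1675 without cadmium 6 and 1806 without control 6.

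Apoptosis and innate immunity genes shifted upward in polystyrene-fed brains. Of 167 apoptosis genes 18 rose and 2 fell (27 and 4 adjusted over the list alone, camera adjusted p = 0.00333, adjusted p = 0.775 with an estimated correlation). That list call was lost without control 5 (camera adjusted p = 0.0617). The caspase inhibitor Baculoviral IAP repeat-containing protein 3 (Cluster-2499.126263, 14.3 ± 8.04 against 1.61 ± 0.503 CPM, log2 fold change 3.15 ± 0.52, edgeR adjusted p = 0.00339) was among them. The number rising was 5 without polystyrene 6, 6 without polystyrene 5, 8 without control 5 and 11 without cadmium 4 or control 6, that falling 0 without control 4 or polystyrene 4, 1 without cadmium 4 or combined 5 or control 6 or polystyrene 5 or 6 and 4 without combined 4. Immunity genes rose in 49 and fell in 11 of 355 (72 and 13 adjusted over the list alone, camera adjusted p = 3.00e-04, adjusted p = 0.775 with an estimated correlation). Tumor necrosis factor receptor superfamily member 18 (Cluster-2499.86905, 3.56 ± 1.39 against 0.0887 ± 0.0987 CPM, edgeR adjusted p = 0.00137) was among the former. Sodium channel protein 1 brain (Cluster-2499.127194, 24.9 ± 9.8 against 6.18 ± 2.52 CPM, edgeR adjusted p = 0.00411) and Sodium channel protein 60E (Cluster-2499.128525, 7.11 ± 2.88 against 1.96 ± 0.531 CPM, adjusted p = 0.00869), of the family that carries action potentials, rose. Thrombomodulin (7.65 ± 0.933 CPM, at least 114-fold higher, edgeR adjusted p = 0.00132) and the same Inhibitor of apoptosis protein (6.17 ± 1.88 CPM, at least 91.1-fold higher, adjusted p = 2.06e-04) rose from no count. Hemicentin-1 fell to none (at least 358-fold, edgeR adjusted p = 2.07e-04). Zinc transporter ZIP6 (Cluster-2499.61303, 41.03 ± 2.64 against 19.4 ± 4.28 CPM, edgeR adjusted p = 0.0114) and ABCA3 (4.9 ± 1.09 against 0.977 ± 0.658 CPM, adjusted p = 0.00883) rose.

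Mitochondrially encoded clusters moved both ways, 7 of 90 up and 17 down (8 and 32 adjusted over the list alone, camera adjusted p = 3.00e-04, adjusted p = 0.775 with an estimated correlation). Cytochrome b Cluster-2499.82579 rose (92.6 ± 26.9 against 0.133 ± 0.231 CPM, edgeR adjusted p = 5.59e-05) and NADH-ubiquinone oxidoreductase chain 4L fell (23.7 ± 8.69 against 282 ± 117 CPM, adjusted p = 7.41e-04). The number lower was 10 without polystyrene 5. ABC transporters (5 higher and 1 lower of 85) and ciliary genes (1 of 129) shifted upward (camera adjusted p = 0.00776 and 0.0101, adjusted p = 0.775 and 0.859 with an estimated correlation). Nuclear-encoded oxidative phosphorylation (1 of 54 lower) and oxygen carriers (none of 31) shifted downward (camera adjusted p = 0.00776 and 0.0101, adjusted p = 0.775 and 0.775 with an estimated correlation). In that order these calls were lost without control 5 (camera adjusted p = 0.285), without control 5, polystyrene 5 or polystyrene 6 (camera adjusted p up to 0.285), without control 4 or polystyrene 5 (camera adjusted p up to 0.125) and without control 6 or polystyrene 6 (camera adjusted p up to 0.333). The number of higher ABC transporters was 2 without polystyrene 6 and 3 without polystyrene 5 (lower ones 0 without any library but cadmium 4), of ciliary genes 2 without control 6 or polystyrene 4 and of lower oxidative phosphorylation genes 0 without cadmium 4 or 5 or 6 or combined 4 or 5 or 6 or control 4 or polystyrene 4 or 5 or 6 and 2 without control 6. Polystyrene changed 4536 clusters in brain, 2987 upward and 1549 downward. The count was 2791 in a fit of the 6 samples, 2132 without polystyrene 6, 2145 without polystyrene 5 and 2901 without control 6.

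Brains of the combined exposure held 50389.7 ± 14369 CPM of muscle transcripts against 24497 ± 8070.1 in controls, 27185 ± 6825 with cadmium and 24054 ± 6338 with polystyrene. Of 64 muscle genes 5 rose and none fell (21 and 2 adjusted over the list alone, camera adjusted p = 2.32e-05, adjusted p = 0.823 with an estimated correlation). Leaving out 1 library, the number higher was 1 without control 4, 2 without combined 4 or 5 and 12 without control 6. Catchin (Cluster-2499.50561, 142 ± 28.6 against 37.1 ± 15.01 CPM, log2 fold change 1.93 ± 0.34, edgeR adjusted p = 0.00684), from the myosin gene of molluscan catch muscle, was among them. Immunity genes rose in 47 and fell in 9 of 355 (67 and 17 adjusted over the list alone, camera adjusted p = 9.81e-06, adjusted p = 0.823 with an estimated correlation). The number higher was 30 without control 4. Complement C1q-like protein 4 rose (89.03 ± 66.9 against 0.131 ± 0.13 CPM, edgeR adjusted p = 1.24e-04) and a C-type lectin (Cluster-2499.65119, 2.62 ± 1.3 against 13.7 ± 4.7 CPM, adjusted p = 0.00251) fell. Caspase-3 and the initiator Caspase-8 (Cluster-2499.123163, 3.14 ± 2.09 against 27.6 ± 0.478 CPM, edgeR adjusted p = 0.00968) fell (Caspase-3 1.95 ± 0.289 against 22.7 ± 5.48 CPM, adjusted p = 3.80e-04). The Inhibitor of apoptosis protein (7.3 ± 3.69 CPM, at least 107-fold higher, edgeR adjusted p = 1.96e-04) and the synaptic Metabotropic glutamate receptor 5 (Cluster-2499.20619, 13.6 ± 9.21 CPM, at least 205-fold higher, adjusted p = 0.00364) rose from no count. Hemicentin-1 fell to none (at least 342-fold, edgeR adjusted p = 2.89e-04). The potassium channel Shab (Cluster-2499.111306, 34.7 ± 8.47 against 17.04 ± 3.46 CPM, edgeR adjusted p = 0.0131) rose.

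Mitochondrially encoded clusters rose in 5 and fell in 14 of 90 (7 and 27 adjusted over the list alone, camera adjusted p = 9.81e-06, adjusted p = 0.823 with an estimated correlation). The number lower was 7 without combined 5. The number higher was 2 without control 6, 3 without cadmium 4 or 5 or 6 or combined 5 or 6 or polystyrene 4 or 5 or 6 and 9 without control 5. NADH dehydrogenase subunit 5 (Cluster-2499.88267, 295 ± 82.4 against 83.5 ± 37.6 CPM, edgeR adjusted p = 0.00418) rose. Cytochrome b Cluster-2499.80522 fell (2.7 ± 2.09 against 555 ± 519.8 CPM, edgeR adjusted p = 0.00776). P450 2C20 (Cluster-2499.88450, 21.3 ± 8.71 against 4.75 ± 0.949 CPM, edgeR adjusted p = 0.00233) rose, as did ABCA3 (5.04 ± 1.66 against 0.977 ± 0.658 CPM, adjusted p = 0.0107). Heat shock genes shifted upward with 3 of 36 higher (7 adjusted over the list alone, camera adjusted p = 4.51e-04, adjusted p = 0.951 with an estimated correlation), lost without control 5 (camera adjusted p = 0.0949), and the number higher was 0 without control 5 and 1 without control 4. Oxygen carriers shifted downward with 1 higher and 1 lower of 31 (camera adjusted p = 0.0483, adjusted p = 0.951 with an estimated correlation), lost in 5 of 12 omissions (camera adjusted p up to 0.225), the number lower being 2 without combined 4 or control 5. Combined exposure changed 2513 clusters in brain, 1367 up and 1146 down. The count was 1340 in a fit of the 6 samples, 1502 without combined 5 and 1656 without control 4.

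**Figure D3:**
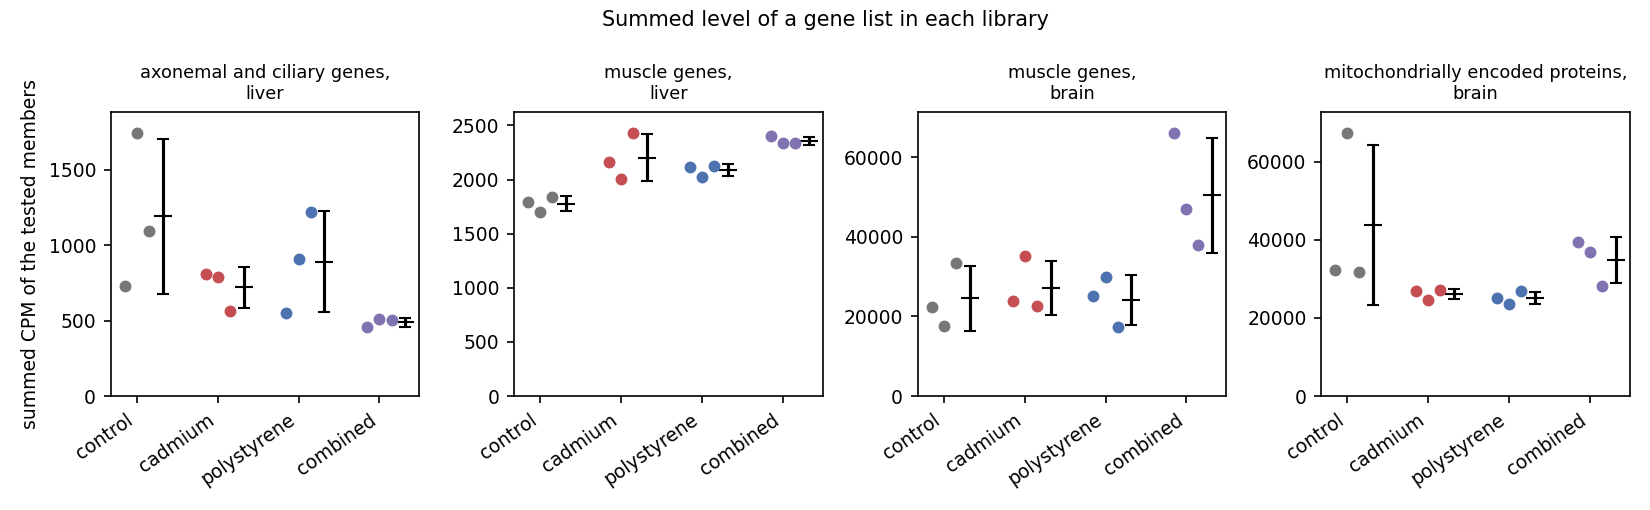
Summed CPM of the tested members of 3 gene lists in each library by treatment, for ciliary and muscle genes in liver and muscle and mitochondrially encoded genes in brain, with group mean and SD in black. The muscle list in brain reached 37991 to 66137 CPM in the combined group and 17702 to 33417 CPM in the controls.

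Against cadmium alone, brains of the combined exposure held less of the mitochondrial Cytochrome b Cluster-2499.82579 (0.451 ± 0.229 against 85.5 ± 15.3 CPM, edgeR adjusted p = 1.13e-04) and Cytochrome c oxidase subunit 1 (1.22 ± 0.282 against 253 ± 47.4 CPM, adjusted p = 1.13e-04). They held less of the C-type lectin (2.62 ± 1.3 against 18.5 ± 0.782 CPM, edgeR adjusted p = 0.00102). Heat shock protein 70 B2 was lower too (11.6 ± 5.78 against 118 ± 90.7 CPM, edgeR adjusted p = 0.0131). Its call was lost without combined replicate 5 or 6 (edgeR adjusted p up to 0.0594). Muscle genes shifted upward, 4 higher and 1 lower of 64 (20 and 2 adjusted over the list alone, camera adjusted p = 1.26e-04, adjusted p = 0.911 with an estimated correlation). Chaperones of the endoplasmic reticulum (2 of 18 lower) and ribosomal proteins (1 of 102) shifted downward (camera adjusted p = 7.49e-05 and 7.49e-05, adjusted p = 0.206 and 0.911 with an estimated correlation). So did oxygen carriers (1 of 31) and apoptosis genes (4 of 167; camera adjusted p = 0.024 and 0.0329, adjusted p = 0.911 and 0.911 with an estimated correlation). In total 1785 clusters differed, 802 higher and 983 lower. Leaving out 1 library gave 780 without cadmium 4, 896 without combined 5, 963 without cadmium 6, 1011 without cadmium 5 and 2816 without control 5.

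Against polystyrene alone, apoptosis genes were lower in 10 and higher in 2 of 167 (17 and 2 adjusted over the list alone, camera adjusted p = 0.026, adjusted p = 0.938 with an estimated correlation). Among them were Caspase-3 (1.95 ± 0.289 against 15.8 ± 7.63 CPM, edgeR adjusted p = 9.87e-04) and Baculoviral IAP repeat-containing protein 3 Cluster-2499.126263 (1.94 ± 0.442 against 14.3 ± 8.04 CPM, adjusted p = 0.00798). Complement C1q-like protein 4 was higher (89.03 ± 66.9 against 1.01 ± 0.0726 CPM, edgeR adjusted p = 3.60e-04) and Cytochrome c oxidase subunit 1 lower (1.22 ± 0.282 against 378 ± 170.4 CPM, adjusted p = 8.86e-05). The latter is a fragment cluster, while all tested mitochondrially encoded clusters summed to 34816 ± 5876 against 25154 ± 1625 CPM. Muscle genes shifted upward (4 of 64, 14 adjusted over the list alone, camera adjusted p = 2.49e-04). So did oxidative phosphorylation (0 of 54) and proteasome subunits (1 of 40, camera adjusted p = 0.026 and 0.026). Ciliary genes shifted downward (9 of 129, camera adjusted p = 3.34e-07). With an estimated correlation camera gave each list an adjusted p = 0.938. Here 2247 clusters differed, 797 higher and 1450 lower. The count was 887 without polystyrene 6, 908 without polystyrene 5, 918 without combined 5, 1347 without combined 4 and 3877 without control 5.

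In the test of additivity in brain, Sodium channel protein 1 brain stood at 6.18 ± 2.52 CPM in controls, 10.5 ± 1.95 with cadmium, 24.9 ± 9.8 with polystyrene and 9.42 ± 1.75 with both (departure -2.17 ± 0.48, edgeR adjusted p = 0.0171). Cytochrome c oxidase subunit 1 stood at 7.11 ± 5.05 CPM in controls, 253 ± 47.4 with cadmium, 378 ± 170.4 with polystyrene and 1.22 ± 0.282 with both (departure -13.42 ± 0.79, edgeR adjusted p = 4.67e-06). Baculoviral IAP repeat-containing protein 3 (Cluster-2499.126263, departure -4.35 ± 0.71, edgeR adjusted p = 0.00341) and Sodium channel protein 60E (departure -2.53 ± 0.52, adjusted p = 0.0114) lay below the sum too. The muscle protein Myosin-16 (Cluster-2499.75439, departure 1.77 ± 0.34, edgeR adjusted p = 0.00775) and NADH-ubiquinone oxidoreductase chain 4L (departure 5.29 ± 0.58, adjusted p = 3.25e-04) lay above it. Apoptosis genes departed downward in 13 and upward in 1 of 167 (21 and 4 adjusted over the list alone, camera adjusted p = 5.50e-04, adjusted p = 0.819 with an estimated correlation). Immunity genes did in 36 and 12 of 355 (53 and 16 adjusted over the list alone, camera adjusted p = 0.00114, adjusted p = 0.819 with an estimated correlation). Ciliary genes, ABC transporters and endoplasmic reticulum chaperones departed downward in 5, 4 and 2 (camera adjusted p = 0.00741, 0.0216 and 0.0321, adjusted p = 0.819, 0.819 and 0.819 with an estimated correlation). Mitochondrially encoded clusters departed upward in 13 and downward in 9 of 90 (camera adjusted p = 0.0173, adjusted p = 0.819 with an estimated correlation). In all, 3824 clusters departed, 1438 above and 2386 below the sum. Their number was 1922 without cadmium 4, 2199 without polystyrene 6, 2249 without combined 5, 2386 without polystyrene 5 and 2408 without cadmium 6.

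The 3 treatments of a tissue were set against the same 3 controls, and many clusters were called alike. In liver, cadmium and polystyrene shared 258 higher and 351 lower clusters, cadmium and combined exposure 327 and 517, and polystyrene and combined exposure 439 and 486. Independent lists would share 14.6 and 15.6, 26.5 and 34.01, and 25.2 and 29.4. Opposite calls numbered 6, 9 and 7. All 3 treatments raised 176 and lowered 294 (0.418 and 0.529 for independent lists). Across genes, which are not independent replicates, the log2 fold changes of the 3 pairs had covariances of 0.733, 0.858 and 0.811 and correlations of 0.65, 0.63 and 0.63. Simulated unchanged groups gave 0.113, 0.114 and 0.113 and 0.50, 0.50 and 0.50. In brain, cadmium and polystyrene shared 939 higher and 431 lower clusters, cadmium and combined exposure 547 and 427, and polystyrene and combined exposure 703 and 401. Independent lists would share 77.5 and 27.1, 35.5 and 20.04, and 63.8 and 27.7. Opposite calls numbered 12, 13 and 21. All 3 treatments raised 394 and lowered 233 (1.65 and 0.485 for independent lists). Across genes, which are not independent replicates, the log2 fold changes of the 3 pairs had covariances of 1.12, 1.03 and 1.002 and correlations of 0.68, 0.64 and 0.62. Simulated unchanged groups gave 0.127, 0.128 and 0.129 and 0.50, 0.50 and 0.50. P450 3A24 and SCO-spondin were lower than in controls in the livers of all 3 treatments, and Thrombomodulin and ABCA3 were higher in the brains. Since 3 controls cannot be split into sets of 2 libraries, part of the excess may come from the shared controls.

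The difference between the responses of brain and liver was tested in a fit of all 24 samples. Under cadmium, the Inhibitor of apoptosis protein Cluster-2499.76001 went from 2.32 ± 0.86 to 5.46 ± 0.983 CPM in brain and from 10.2 ± 0.917 to 2.78 ± 0.918 CPM in liver (difference 3.10 ± 0.44, edgeR adjusted p = 4.98e-04). ABCA3 (difference 2.76 ± 0.52, edgeR adjusted p = 0.0048) and Cytochrome c oxidase subunit 1 (difference 5.91 ± 0.82, adjusted p = 9.76e-04) were relatively higher in brain. Cytochrome b (Cluster-2499.80522, difference -10.41 ± 1.83, edgeR adjusted p = 0.00636) was relatively lower. Mitochondrially encoded clusters were relatively higher in 3 and lower in 13 of 93 (camera adjusted p = 1.54e-10, adjusted p = 0.466 with an estimated correlation). Immunity genes were in 19 and 5 of 550 (camera adjusted p = 0.0112, adjusted p = 0.758 with an estimated correlation). Ciliary genes, ABC transporters, neurotransmitter enzymes and sperm and testis genes were higher in 2, 1, 3 and 1 (neurotransmitter enzymes lower in 1; camera adjusted p = 6.89e-05, 0.00256, 0.0111 and 0.0111, adjusted p = 0.758, 0.758, 0.758 and 0.758 with an estimated correlation). In all 1755 clusters differed, 1113 relatively higher in brain and 642 lower. The count was 1036 without liver control replicate 2, 1053 without liver cadmium replicate 1, 1115 without liver cadmium replicate 2 and 1141 without brain cadmium replicate 4.

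Under polystyrene, Cartilage matrix protein went from 304 ± 49.4 to 188 ± 16.2 CPM in brain and from 75.2 ± 7.3 to 120.4 ± 2.62 CPM in liver (difference -1.37 ± 0.23, edgeR adjusted p = 0.00153). Zinc transporter ZIP6 went from 15.2 ± 3.45 to 32.6 ± 2.19 CPM in brain and from 5.37 ± 0.14 to 4.17 ± 0.469 CPM in liver (difference 1.46 ± 0.31, edgeR adjusted p = 0.00989). Cytochrome c oxidase subunit 1 (difference 7.0 ± 0.84, edgeR adjusted p = 2.86e-04) was relatively higher in brain. Myosin-16 (difference -2.16 ± 0.34, edgeR adjusted p = 0.00106) was relatively lower. Apoptosis genes were relatively higher in 9 of 169 and ABC transporters in 3 (camera adjusted p = 0.00296 and 0.0255). Transposable elements were in 10 (lower in 1) and ciliary genes in 0 (camera adjusted p = 0.0482 and 8.25e-05). Mitochondrially encoded clusters were lower in 9 and higher in 5 (camera adjusted p = 2.25e-05). With an estimated correlation camera gave each list an adjusted p = 0.986. The count was 2238, with 1354 relatively higher in brain and 884 lower. Leaving out 1 library gave 1282 without liver control replicate 2, 1297 without liver polystyrene replicate 2, 1408 without brain polystyrene replicate 6, 1412 without liver polystyrene replicate 1 and 1449 without brain polystyrene replicate 5.

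Under combined exposure, Cilia- and flagella-associated protein 61 went from 13.2 ± 3.19 to 11.7 ± 0.917 CPM in brain and from 8.19 ± 4.75 to 1.04 ± 0.332 CPM in liver (difference 2.79 ± 0.52, edgeR adjusted p = 0.00462). The C-type lectin went from 10.7 ± 3.74 to 2.09 ± 1.04 CPM in brain and from 2.46 ± 0.983 to 3.83 ± 1.39 CPM in liver (difference -2.98 ± 0.53, edgeR adjusted p = 0.00355). Protein 77 of that family (difference 3.19 ± 0.65, edgeR adjusted p = 0.0111) and Spermatogenesis-associated protein 1 (difference 3.01 ± 0.59, adjusted p = 0.00804) were relatively higher in brain. Cytochrome b (Cluster-2499.80522, difference -9.21 ± 1.66, edgeR adjusted p = 0.00844) was relatively lower. Of 131 ciliary genes 11 were relatively higher and 0 lower (56 and 2 adjusted over the list alone, camera adjusted p = 1.23e-18, adjusted p = 0.621 with an estimated correlation). Of sperm and testis genes 2, ABC transporters 1 and heat shock genes 2 were higher (camera adjusted p = 7.55e-05, 0.0400 and 0.0400, adjusted p = 0.621, 0.867 and 0.867 with an estimated correlation). Of mitochondrially encoded clusters 12 were lower (camera adjusted p = 6.13e-05, adjusted p = 0.621 with an estimated correlation). Here 1557 clusters differed, 942 relatively higher in brain and 615 lower. The count was 882 without liver control replicate 2, 948 without liver combined replicate 2 and 958 without liver combined replicate 3.

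Among the unexposed samples, brain carried Pro-neuropeptide Y (Cluster-2499.37181, 358 ± 279.9 CPM, at least 4006-fold higher, edgeR adjusted p = 6.82e-05), with no count in liver. It held more Synaptotagmin-1 (Cluster-2499.105793, 191 ± 67.8 against 16.3 ± 1.14 CPM, edgeR adjusted p = 8.80e-13), the calcium sensor of synaptic vesicles, and more of the digestive Chymotrypsinogen 2 (Cluster-2499.37183, 1618 ± 879 against 0.293 ± 0.12 CPM, adjusted p = 4.09e-14). Lower in brain were Apolipophorins (Cluster-2499.87715, 0.542 ± 0.219 against 10559 ± 1886 CPM, log2 fold change -14.22 ± 0.43, edgeR adjusted p = 2.41e-17), lipid carriers of the blood, and P450 4F2 (Cluster-2499.88596, 1.35 ± 0.431 against 157 ± 28.6 CPM, adjusted p = 2.84e-15). So was Catalase (Cluster-2499.89267, 34.4 ± 4.57 against 239 ± 32.8 CPM, edgeR adjusted p = 1.22e-13), which breaks down hydrogen peroxide. The muscle genes Myosin regulatory light chain (Cluster-2499.90000, 1271 ± 287 against 52.99 ± 7.49 CPM, edgeR adjusted p = 8.37e-13) and Titin (Cluster-2499.99408, 166 ± 30.8 against 22.7 ± 1.54 CPM, adjusted p = 4.39e-12) were higher in brain. Neuronal genes (186 higher and 30 lower of 271) and muscle genes (46 higher and 6 lower of 66) were higher in brain. Lysosomal proteins (7 higher and 94 lower of 126), digestive enzymes (54 higher and 105 lower of 214), lipid metabolism (32 higher and 117 lower of 201), UDP-glucuronosyl- and sulfotransferases (7 higher and 33 lower of 54) and neurotransmitter enzymes (14 higher and 28 lower of 53) were lower. These calls held with an estimated correlation (camera adjusted p = 0.0168, 0.0168, 0.00522, 0.00684, 0.00522, 0.00522 and 0.0212). Those of cytochrome P450, immunity genes, ABC transporters, glutathione S-transferases, ribosomal proteins and ciliary genes were lost (camera adjusted p = 3.30e-04, 1.57e-06, 1.98e-05, 0.00348, 3.30e-04 and 6.56e-04, adjusted p = 0.347, 0.0567, 0.205, 0.108, 0.711 and 0.711 with an estimated correlation). Altogether 39192 of 78809 clusters differed, 18510 higher and 20682 lower in brain.

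In the 6 comparisons of a treatment with its controls, 13 further lists showed no shift in any. Their member calls, higher and lower over these comparisons, were 37 and 11 for collagens and matrix, 43 and 43 for transposable elements, 0 and 2 for proteasome subunits, 0 and 7 for glutathione S-transferases, 2 and 8 for UDP-glucuronosyl- and sulfotransferases, 12 and 12 for lysosomal proteins, 10 and 1 for metal ion transport and storage, 39 and 15 for digestive enzymes, 3 and 2 for cell cycle, 0 and 0 for glycolysis, 30 and 19 for cytochrome P450, 5 and 2 for antioxidant enzymes and 15 and 11 for lipid metabolism, with camera adjusted p from 0.058 upward. Algal photosynthesis genes had 3 tested members, none called, and no cluster carried the name metallothionein.

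Acetylcholinesterase ends cholinergic signalling, and its most abundant clusters did not pass the test under any treatment. In liver (Cluster-2499.85211) the log2 fold changes with cadmium, polystyrene and both were 0.09 ± 0.11, -0.02 ± 0.11 and 0.10 ± 0.11 (edgeR adjusted p = 0.739, 0.945 and 0.645). In brain (Cluster-2499.84319) they were 0.29 ± 0.22, 0.02 ± 0.22 and 0.28 ± 0.22 (edgeR adjusted p = 0.538, 0.977 and 0.572). Combined exposure against cadmium and against polystyrene gave 0.01 ± 0.11 and 0.13 ± 0.11 (edgeR adjusted p = 0.971 and 0.677) in liver and 0.00 ± 0.22 and 0.26 ± 0.22 (adjusted p = 0.999 and 0.593) in brain. The departures from additivity were 0.04 ± 0.15 (edgeR adjusted p = 0.952) and -0.02 ± 0.31 (adjusted p = 0.985). The differences between tissues were 0.79 ± 0.63, 0.65 ± 0.64 and 0.01 ± 0.61 (edgeR adjusted p = 0.612, 0.691 and 0.99998). The cluster named for liver (Cluster-2499.85211, 0.875 ± 0.491 against 60.6 ± 3.35 CPM, edgeR adjusted p = 3.21e-09) was lower in brain than in liver among controls. The 70 kDa heat shock gene with the smallest p did not pass with cadmium (Cluster-2499.57688), polystyrene (Cluster-2499.105905) in liver or with polystyrene (Cluster-2499.64532) and both (Cluster-2499.78257) in brain (log2 fold change 2.82 ± 0.72, -1.08 ± 0.46, 1.03 ± 0.45 and -0.57 ± 0.23, edgeR adjusted p = 0.0768, 0.242, 0.192 and 0.217). The first, at 62.1 ± 2.01 against 8.79 ± 0.415 CPM, passed without combined replicate 1 or polystyrene replicate 1 (edgeR adjusted p = 0.0303 and 0.0312), in a fit of the 6 samples and with DESeq2's Wald test. A 70 kDa gene passed with both in liver (Cluster-2499.75467, 15.9 ± 3.46 against 9.09 ± 1.75 CPM, edgeR adjusted p = 0.0272, and up to 0.0906 in 5 of 12 omissions).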

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

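The tests of the single control library, of a single other tissue, of brain control replicate 5, of mitochondrial variants and of more muscle were chosen only after the result was seen, and those of reads moving, inherited differences, a varying muscle share and the splits before.

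The response to cadmium differed between brain and liver in 1755 clusters. Only the real split of 25 gave as many, the highest other giving 679. Splits also remove each tissue's response, so they cannot decide about chance. Without 1 library it was 1036 (liver control 2), 1053 (liver cadmium 1), 1115 (liver cadmium 2) and 1141 (brain cadmium 4) clusters. Among the named genes the response was higher in brain than in liver, with edgeR adjusted p in parentheses, for Inhibitor of apoptosis protein Cluster-2499.76001 (4.98e-04), Cytochrome c oxidase subunit 1 Cluster-2499.87407 (9.76e-04), Inhibitor of apoptosis protein Cluster-2499.95251 (0.00111), ABCA3 Cluster-2499.69072 (0.0048), Cytochrome b Cluster-2499.82579 (0.0209) and Perivitellin-2 67 kDa subunit Cluster-2499.69505 (0.0234). It was lower in brain than in liver by edgeR's adjusted p for Cytochrome b Cluster-2499.80522 (0.00636), NADH-ubiquinone oxidoreductase chain 4L Cluster-2499.84200 (0.00711) and Glutaredoxin Cluster-2499.63316 (0.0302).

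Responses to polystyrene differed between the tissues in 2238 clusters. Only the real split of 25 gave as many, the highest other giving 71, which for the same reason cannot decide about chance. Without 1 library it was 1282 (liver control 2), 1297 (liver polystyrene 2) and 1408 (brain polystyrene 6) clusters. It was 1412 without liver polystyrene 1 and 1449 without brain polystyrene 5. Among the named genes the response was higher in brain than in liver, with edgeR adjusted p in parentheses, for SCO-spondin Cluster-2499.89586 (1.34e-05), Cytochrome c oxidase subunit 1 Cluster-2499.87407 (2.86e-04), Inhibitor of apoptosis protein Cluster-2499.95251 (4.78e-04), Cytochrome b Cluster-2499.82579 (0.00163), tumor necrosis factor receptor superfamily member 18 Cluster-2499.86905 (0.00259), Zinc transporter ZIP6 Cluster-2499.61303 (0.00989), Hemocytin Cluster-2499.87352 (0.0151) and ABCA3 Cluster-2499.69072 (0.0499). It was lower in brain than in liver by edgeR's adjusted p for Myosin-16 Cluster-2499.75439 (0.00106), Cartilage matrix protein Cluster-2499.87991 (0.00153), Glutaredoxin Cluster-2499.63316 (0.00403), Collagen alpha-4(VI) chain Cluster-2499.80169 (0.0213) and NADH-ubiquinone oxidoreductase chain 4L Cluster-2499.84200 (0.0227).

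With combined exposure the tissues differed in 1557 clusters. Only the real split of 25 gave as many, the highest other giving 666, which again cannot decide about chance. Without 1 library it was 882 (liver control 2), 948 (liver combined 2) and 958 (liver combined 3) clusters. Among the named genes the response was higher in brain than in liver, with edgeR adjusted p in parentheses, for Perivitellin-2 67 kDa subunit Cluster-2499.69505 (9.80e-05), Inhibitor of apoptosis protein Cluster-2499.95251 (3.52e-04), Cilia- and flagella-associated protein 61 Cluster-2499.59043 (0.00462), Spermatogenesis-associated protein 1 Cluster-2499.108246 (0.00804), Cilia- and flagella-associated protein 77 Cluster-2499.52633 (0.0111) and ABCA3 Cluster-2499.69072 (0.0122). It was lower in brain than in liver by edgeR's adjusted p for C-type lectin Cluster-2499.65119 (0.00355), Cytochrome b Cluster-2499.80522 (0.00844), Zinc transporter ZIP2 Cluster-2499.79570 (0.0321) and Collagen alpha-4(VI) chain Cluster-2499.80169 (0.0427).

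In liver 178 clusters, 43 with a product name, summed to 2860.1 to 6935 CPM in the controls and 41.2 to 92.2 CPM in every treated liver. Chosen without control replicate 1, 2 or 3, such clusters numbered 162, 86 and 128. Of them 147, 86 and 125 stood above all 9 treated livers in the control left out (90.7% for the first, interval 85.2 to 94.7). This argues against a single control library for these clusters only. Without control 2 only 78 of the 178 were chosen. A single other tissue with 1 fixed profile would keep the ratios between controls, but the log2 ratio of control replicate 2 to 1 spread 2.6 times as wide as in clusters of the same level (interval 1.86 to 3.62); how far such a profile varies between snails was not measured, so other tissue in the control livers cannot be told apart from a response. Neither can inherited differences, as the labels do not say whether liver and brain came from the same animals and only 63 of the 178 clusters were tested in brain, where 31 (49.2%, interval 36.4 to 62.1) were lower in treated samples. Reads moving to clusters of the same database match cannot be told apart from a loss, since only 15.7% had such a partner (median rise over loss -0.69), and a response to the exposures, or another difference in how the control livers were taken, stays open and was not tested.

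Mitochondrially encoded clusters rose and fell in the treated brains. The library of brain control replicate 5 is argued against as the whole cause, since 78.1% of 73 calls over the 3 treatments stood without it. The interval (66.9 to 86.9) takes calls that share controls as independent, so it is too narrow. Mitochondrial variants that differ between animals, assembled as separate clusters, may add to this and cannot be told apart from a response: in liver the called clusters varied 1.55 times as much within groups as the others (interval 0.969 to 2.09).

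Muscle genes shifted upward in the brains of the combined exposure, where 5 of 64 passed (1 without control 4, 2 without combined 4 or 5 and 12 without control 6; camera adjusted p = 2.32e-05, adjusted p = 0.823 with an estimated correlation), with 31 of 33 members of 50 CPM or more positive (93.9%) and a median log2 fold change of 0.97. This share restates the shift that prompted the test, as does the sum of 50389.7 ± 14369 against 24497 ± 8070.1 CPM in controls, so more muscle tissue in those samples cannot be told apart from a rise within brain cells. A muscle share that varies from sample to sample in every group stays open, as the members correlated at 0.397 on average across the 12 libraries once group means were removed.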

How the results depend on the processing

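All alternatives here were planned before the data were examined. The counts of calls below are given as the main value, then with DESeq2's Wald test, then with no filter on low counts: 1930, 3567 and 5436 for cadmium in liver, 1750, 3178 and 4784 for polystyrene in liver, 3482, 5605 and 7214 for combined in liver, 2782, 4977 and 5972 for cadmium in brain, 4536, 7089 and 7619 for polystyrene in brain, 2513, 4815 and 5995 for combined in brain, 1393, 3300 and 4882 for combined against cadmium in liver, 736, 2273 and 3902 for combined against polystyrene in liver, 1785, 3460 and 4493 for combined against cadmium in brain, 2247, 4418 and 5327 for combined against polystyrene in brain, 995, 2589 and 3923 for additivity in liver, 3824, 6583 and 7067 for additivity in brain, 1755, 3587 and 3633 for the tissue difference under cadmium, 2238, 4108 and 3976 for that under polystyrene and 1557, 3615 and 3715 for that under both. In a fit of only the 6 samples compared the counts were 2267 for combined in liver, 2791 for polystyrene in brain, 1340 for combined in brain and 623 for combined against cadmium in liver. Over the 6 treatments 34 list calls stood, 0 with an estimated correlation, where camera gave 7 at an unadjusted p under 0.05 of 168. The cause was not tested, except that simulated counts gave DESeq2 41 false of 158 calls for cadmium in liver, against 5 of 106 with edgeR. DESeq2's size factors, the stricter filter and the added log2 fold change left these counts within 1.5 times of their main values.

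With 1 library left out the lowest and highest counts were 568 and 2969 for cadmium in liver, 570 and 2708 for polystyrene in liver, 1058 and 3962 for combined in liver, 1280 and 3508 for cadmium in brain, 2132 and 5253 for polystyrene in brain, 1502 and 2722 for combined in brain, 442 and 2007 for combined against cadmium in liver, 219 and 1141 for combined against polystyrene in liver, 780 and 2816 for combined against cadmium in brain, 887 and 3877 for combined against polystyrene in brain, 448 and 1723 for additivity in liver, 1922 and 4001 for additivity in brain, 1036 and 1918 for the tissue difference under cadmium, 1282 and 2422 for that under polystyrene and 882 and 1741 for that under both, and 35967 and 41164 for brain against liver. Of 128 named calls 124 were kept in every omission, against 526 of the rule's 978, which reflects their choice, as may the shares below.

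Named calls kept their side of the threshold in 128 of 128 with DESeq2's Wald test, 126 with no filter, 128 with its size factors, 128 with the stricter filter, 113 with the added fold change, 87 of 95 with 6 samples, and none reversed. Of 19 named genes without a call 1, Heat shock protein 70 B2 with cadmium in liver, gained one with DESeq2's Wald test, with 6 samples and in 2 omissions. Calls lost were, with no filter: Hemocyanin 2, polystyrene in liver; Heat shock protein 70 B2, combined against cadmium in brain (edgeR adjusted p up to 0.209); and with 6 samples: SCO-spondin, polystyrene in liver; Tissue-type plasminogen activator, Dynein axonemal heavy chain 10 and Heat shock protein 70 B2 Cluster-2499.75467, combined in liver; ABCA3 and Shab, combined in brain; ZIP8, combined against cadmium in liver; Heat shock protein 70 B2, combined against cadmium in brain (adjusted p up to 0.132). Of the named genes only acetylcholinesterase changed sign, in comparisons where it was not called. Without 1 library, Cluster-2499.85211 had log2 values of -1.05 to 0.600 in the tissue difference under both. In liver it had -0.0737 to 0.067 in combined against cadmium and -0.0426 to 0.0927 in additivity. In brain, Cluster-2499.84319 had -0.0624 to 0.174 with polystyrene and -0.314 to 0.0826 in additivity. It had -0.269 to 0.126 in combined against cadmium and -0.00653 to 0.389 in combined against polystyrene. With the replicate block as a term Cluster-2499.85211 had -0.0422 in the tissue difference under both.

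Same-numbered samples of a tissue did not deviate together (correlations -0.0976 to 0.109 in liver and -0.124 to 0.133 in brain), so the numbers were not taken to pair them. The replicate block gave 1497, 1388 and 2803 calls for the liver treatments, 2129, 3730 and 2031 for the brain ones and 35 list calls (4 in place of 6 for combined in liver and 8 in place of 5 for combined in brain), and kept 118 of 119 named calls. With 3 samples per group and the spread seen here, changes of fold 2 were mostly missed in simulated counts.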

Other observations

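The immune GTPase family IMAP was chosen only after the result was seen, as were the counts between tissues, while the splits were planned. These GTPases act in the survival of lymphocytes in vertebrates, and 194 clusters carried the name. Their share of the immunity list's shift was not tested. In brain their summed level was 218 ± 37.8 CPM in controls, 410.4 ± 29.2 with cadmium, 427 ± 7.94 with polystyrene and 437 ± 93.2 with both (mean ± SD, n = 3). Of 110 tested, 22 were higher and 3 lower, 30 were higher and 2 lower and 25 were higher and 1 lower in that order, 22.7%, 29.1% and 23.6% called against 3.34%, 7.04% and 2.77% of other named clusters. In liver the sum was 360.5 ± 13.2 CPM in controls and 361 ± 16.5, 405 ± 26.1 and 337 ± 28.2 with the treatments, with 3 higher and 4 lower, 7 higher and 5 lower and 4 higher and 6 lower of 101, 6.93%, 11.9% and 9.9% called against 3.3%, 2.71% and 6.71% of other named clusters.

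Other clusters moved in all 3 treatments by a log2 fold change of over 3. In liver 83 rose from a sum of 8.45 to between 243 and 574 CPM, and in brain 279 rose from 35.8 to between 1099.7 and 1481 CPM and 167 fell from 1774 to between 24.7 and 67.8 CPM. Of clusters called in both tissues, 65 moved the same way and 49 opposite ways with cadmium (independent lists 22.6 and 22.1), 64 moved the same way and 71 opposite ways with polystyrene (independent lists 33.1 and 31.1) and 108 moved the same way and 59 opposite ways with both (independent lists 35.7 and 36.3).

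The samples of 2 groups of 3 split in only 10 ways, too few for a share under 0.05; the real count and the highest of the other splits were 1930 and 1 for cadmium in liver, 1750 and 0 for polystyrene in liver, 3482 and 0 for combined in liver, 2782 and 1 for cadmium in brain, 4536 and 0 for polystyrene in brain, 2513 and 0 for combined in brain, 1393 and 2 for combined against cadmium in liver, 736 and 1 for combined against polystyrene in liver, 1785 and 0 for combined against cadmium in brain, 2247 and 0 for combined against polystyrene in brain and 39192 and 1 for brain against liver in controls. For additivity only the real split of 25 in each tissue gave as many calls. The real and highest other counts were 995 and 1 in liver and 3824 and 243 in brain. These splits shuffled samples over all groups of the tissue, which also removes the responses to each exposure. They therefore cannot decide about chance.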
